A study of Arabidopsis thaliana with 42 samples.

How the data were processed

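The libraries came from entire seeds of 3 Arabidopsis lines (cyp, qko and pad3) imbibed with conidia of Alternaria brassicicola Abra43 or with water, per the labels, and were sequenced as paired ends on a DNBseq instrument. The labels describe 14 groups of 3 libraries: cyp on days 3, 6 and 10 and qko and pad3 on days 3 and 6, each inoculated and non inoculated. Per the submitters' processing notes, transcripts were quantified with Salmon; its version, the transcript sets and the genome builds are not given in the sources used here. 2 deposited tables held estimated counts, 1 for plant and 1 for fungal transcripts, with 42 columns each. The plant table had 48268 transcript models, and 47.3% of its values were not whole; the fungal table had 12370, with 12.5% not whole. The count columns carried short names for inoculated and healthy libraries, which were matched to the labels by line, day and replicate number. In the fungal table, 3 water columns (pad3 day 6 replicate 3, qko day 6 replicates 1 and 2) were not used, because their few decimal values left the unit open.

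From these values, plant transcripts were summed to 27587 genes and rounded to whole numbers, and fungal counts were rounded likewise. A reference gene table (TAIR10.1) served for gene symbols only: 27392 genes matched it and 10372 had a symbol. Since the build behind the files is unnamed, no coordinates are given. Counting could have split the reads of near-identical paralogs, so values of CYP71A12 and CYP71A13, CYP79B2 and CYP79B3, light-harvesting, extensin and PDF1.2-like genes, GSTF6 and GSTF7, and AT5G46890 and AT5G46900 are uncertain between the members.

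Depth set the precision. Inoculated libraries held 4.72 to 46.0 M plant counts and water libraries 23.9 to 25.6 M. The fungal share ranged from 1.06 to 86.6% (median 44.3%) in inoculated and from 0.00361 to 0.400% (median 0.00832%) in water libraries. In water libraries the 10 fungal genes with most counts held 8.19 (qko day 6 replicate 3) to 88.42% of fungal counts (median 68.69%), against 5.86 to 12.08% in inoculated ones. Replicates of a group differed by 7.29 to 212.41 times the counting noise (chi-square per degree of freedom), so no library was present more than 1 time within a group. The first 2 principal components held 38.0 and 23.1% of the variance.

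Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr with a minimum count of 10, 1 mean per group, and quasi-likelihood F tests, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. 21862 plant genes were tested with 28 residual degrees of freedom and 10266 fungal genes, in the inoculated libraries alone, with 14. The comparisons were inoculated against water in each line and day, differences of that response between lines, its change between days, lines against each other in water, and fungal genes between lines and days. Scaling to plant or fungal totals makes each gene relative to its own species. Standard errors of log2 fold changes were back-calculated as the size of the log2 fold change over the square root of its F statistic. They thus restate the test. For genes with few counts in a group they do not give the precision of the fold. Where a group had no counts, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts a ratio with a 95% counting interval was used in place of the fitted fold.

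The fungal share was compared as log2 of fungal over plant counts by exact two-sided permutation within days (lines) or within lines (days), with Benjamini-Hochberg adjustment over the 4 tests. Flipping the signs of same-numbered differences was added after the data were seen. The Python version was 3.11.15.

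21 gene lists with 379 genes, of which 373 were tested, were fixed together with groups, tests and alternatives before the data were examined. Each was tested with camera in limma 3.58.1 with its preset inter-gene correlation and again with a correlation estimated from the data, adjusted over the 21 lists of a comparison. The lists covered camalexin, indole and aliphatic glucosinolates, tryptophan, sulfur, salicylic acid, jasmonate, ethylene with jasmonate, pattern-triggered immunity, glutathione transferases, phenylpropanoids, flavonoids, abscisic acid, hypoxia, seed storage, reserve lipid, photosynthesis, cell division, root markers, cell expansion and senescence. Over infection and differences of response, 153 list tests passed with the preset correlation and 40 with the estimated one.

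The genes to name followed a rule. PAD3, CYP79B2, CYP79B3, MYB28 and MYB29 were read in every group. Each infection comparison and each difference of response allowed up to 3 members per list with the largest change among those passing, and the 5 highest and 5 lowest genes passing with a mean of at least 5 CPM in 1 group. For infection, the 3 inoculated libraries also had to lie on 1 side of the 3 water libraries. PR1, PDF1.2 and CYP71A13 were read in every infection comparison. Water comparisons allowed the 5 highest and 5 lowest, and fungal comparisons genes with at least 50 CPM. The text names a part of these.

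Replicate numbers could mark a shared batch, so it was checked whether same-numbered libraries deviated together from their group means. Every correlation exceeded 0.1 only for inoculated and water cyp on day 6 (0.473, 0.19 and 0.344) and for fungal genes of cyp and pad3 on day 6 (0.431, 0.223 and 0.161), so the numbers were taken to pair libraries there alone, from the data and not the labels. Other pairs of groups failed this rule on a low value beside high ones. The highest values among these were in fungal genes of qko on days 6 and 3 (0.008, 0.606 and 0.554) and water cyp and pad3 on day 6 (0.522, 0.052 and 0.462). Smaller ones included fungal genes of cyp on days 6 and 3 (0.196, 0.192 and 0.083) and of qko and pad3 on day 3 (0.013, 0.163 and 0.181). A shared batch was not excluded for any pair of groups that failed the rule.

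The test was tried on simulated data made from the real groups, with 200 changed genes. At a 4-fold change it recovered 85, 78 and 80% of them (inoculated against water in cyp on day 3 and in qko on day 6, and fungal genes of cyp against pad3 on day 3), and at 2-fold 53, 42 and 39%. It called 8, 4 and 4 unchanged genes of 21567, 21568 and 9999. The simulated genes varied independently, each with the same spread in every group. Real groups differ in spread and many had far more than 200 changes, so these rates may not carry over. Alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0 Wald tests, a replicate block, a fit of the compared libraries alone, a minimum log2 change of 1, and each library left out in turn.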

Results

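RNA was sequenced from whole Arabidopsis thaliana seeds that had been imbibed with conidia of Alternaria brassicicola (Abra43), the fungus behind black spot of crucifers, or with water alone. 3 mutant lines, labelled cyp, qko and pad3, were collected 3 and 6 days after sowing, and cyp also on day 10, which gave 14 groups of 3 libraries and 42 libraries in all. No wild-type group was analysed here, so each line was compared with its own water group and with the other lines. Each library was counted against plant and fungal transcripts. Plant counts were 4.72 to 46.0 M per inoculated library and 23.9 to 25.6 M per water library. Fungal counts were 0.257 to 30.6 M per inoculated library and 877 to 101163 in the 18 water libraries used for them. Changes below are log2 fold changes ± SE, with 3 libraries per group, and each infection example had its 3 inoculated libraries all above or all below its 3 water libraries, which chance gives for 10% of genes. The labels do not say that replicates were separate cultures, so the spread between samples behind the p-values may be technical. In the edgeR fits this spread was shared over all groups of the fit, so it is not that of the compared groups alone.

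The genes tied to the lines were examined first. PAD3 (AT3G26830, chromosome 3) encodes the cytochrome P450 of the last step of camalexin synthesis, and is the gene named by the pad3 label. In inoculated pad3 it reached 5.09 ± 0.862 CPM (scaled to the library's plant counts with TMM; SD, n = 3) on day 3 and 45.5 ± 6.73 on day 6. In inoculated cyp it reached 33.3 ± 24.4, 413 ± 49.9 and 205 ± 53.8 CPM on days 3, 6 and 10, and in inoculated qko 14.2 ± 1.16 and 162 ± 12.2 on days 3 and 6. The water groups held 0.315 to 6.15 CPM, the highest in qko on day 6, where replicate 3 had 361 PAD3 counts and replicates 1 and 2 had 46 and 85. PAD3 transcripts were present in the pad3 line, and the labels do not give the kind of mutation, so these counts neither check nor contradict that label. MYB28 (AT5G61420, chromosome 5), a transcription factor that drives aliphatic glucosinolate genes, had no counts in qko water libraries on day 3 and at most 15 counts in any qko library. Its level there was at least 431-fold lower than in pad3 and at least 446-fold lower than in cyp, taking 3 counts over the group as the floor. CYP79B2 (AT4G39950, chromosome 4) and CYP79B3 (AT2G22330, chromosome 2), which turn tryptophan into indole-3-acetaldoxime, were present in every group. On day 6 in water, CYP79B3 stood at 223 ± 32.9 CPM in cyp, 79.1 ± 28.2 in qko and 59.25 ± 7.573 in pad3, and CYP79B2 at 45.4 ± 6.11 in cyp, 67.7 ± 17.3 in qko and 104 ± 11.2 in pad3. MYB29 (AT5G07690) lay between 0.00779 and 1.49 CPM in every group. The labels do not say which genes the cyp and qko lines have lost.

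**Figure D1:**
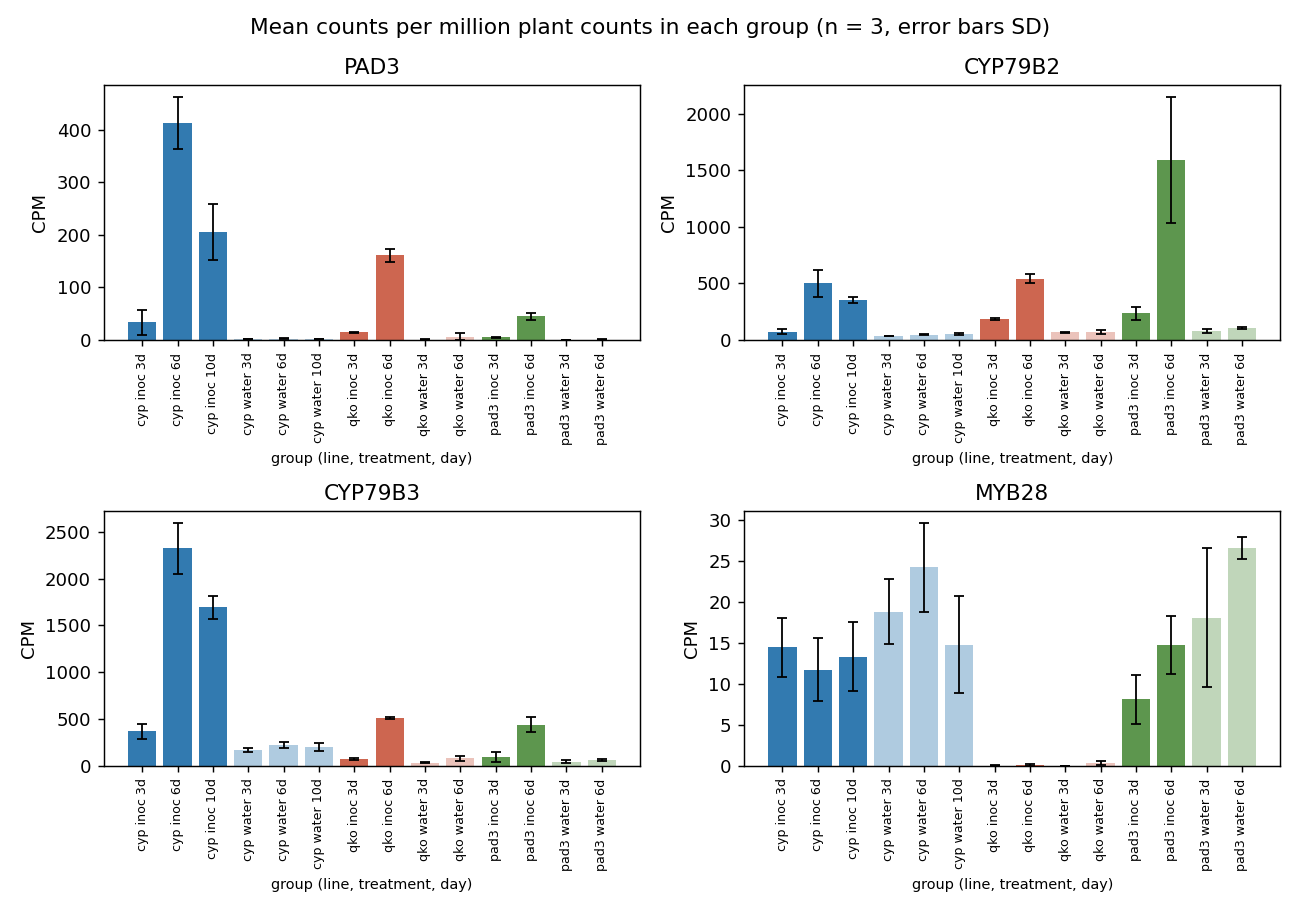
Mean CPM (vertical axis, linear, from 0; error bars SD, n = 3) of PAD3, CYP79B2, CYP79B3 and MYB28 in the 14 groups (horizontal axis), with inoculated groups in full colour and water groups pale. PAD3 reached 413 CPM in inoculated cyp on day 6 and 45.5 in inoculated pad3, and MYB28 was near 0 in every qko group.

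The share of fungal counts asked how much fungal RNA the libraries of each line held relative to plant RNA. More fungal RNA or less plant RNA would both raise it, and the amount of fungus itself was not measured here. In inoculated cyp, fungal transcripts made up 4.99 ± 3.84% of all counts on day 3, 31.0 ± 13.4% on day 6 and 50.6 ± 11.6% on day 10 (SD, n = 3). In qko they made up 60.2 ± 8.24% and 75.4 ± 12.0% on days 3 and 6, and in pad3 30.9 ± 20.6% and 27.3 ± 19.5%. Single inoculated libraries ran from 1.06% (cyp day 3, replicate 1) to 86.6% (qko day 6, replicate 3). The 18 water libraries held 0.00361 to 0.400%, the highest in qko day 6 replicate 3. Over both days, log2 of fungal over plant counts was 4.13 higher in qko than in cyp (6 of 6 same-numbered differences above 0) and 2.65 higher than in pad3 (5 of 6). An exact two-sided permutation test within days gave adjusted p = 0.02 for each, with raw p = 0.005, the smallest that 400 arrangements can give, and 0.01. The cyp against pad3 difference of -1.48 (2 of 6 above 0) had p = 0.18 by the same exact permutation test, and day 6 against day 3 within lines (1.42, 7 of 9 above 0) had p = 0.0542 over 8000 arrangements, with adjusted p = 0.0723. An exact permutation test that flips the signs of same-numbered differences, chosen after the data were seen, gave p = 0.0312 for qko against cyp and 0.0625 for qko against pad3 (adjusted p = 0.0833 for both), so neither passed; 64 flips allow no p below 0.0312. The pooled values hide opposite signs. The cyp against pad3 difference was -3.39 on day 3 and 0.43 on day 6, and day 6 against day 3 was 3.48 in cyp, 1.12 in qko and -0.34 in pad3. The qko against pad3 difference was 1.93 on day 3 and 3.38 on day 6, qko against cyp was 5.32 and 2.95, and cyp day 10 against day 6 was 1.27. Single comparisons allow no exact permutation p below 0.1, and none passed. Without 1 replicate number, 36 arrangements allow no p below 0.0556, so neither line difference could pass; the values were 2.17, 3.80 and 1.99 against pad3 and 3.46, 5.08 and 3.86 against cyp without replicates 1, 2 and 3.

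**Figure D2:**
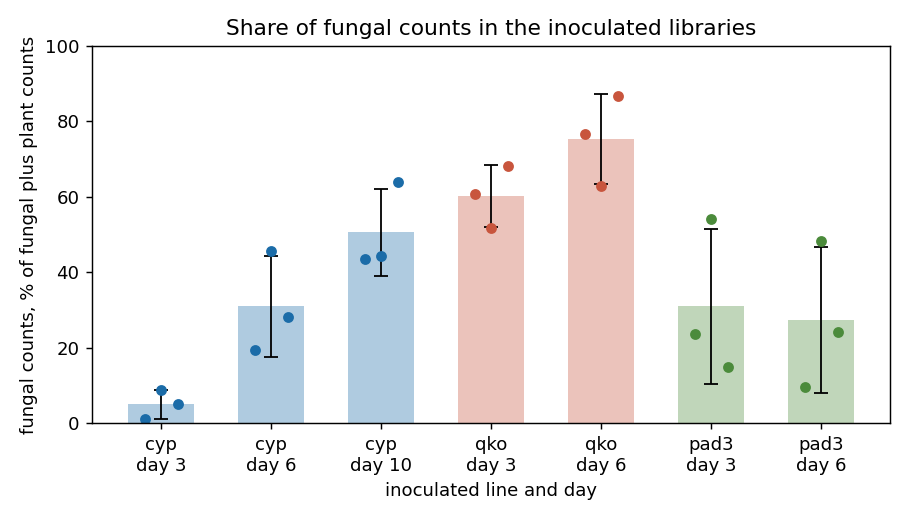
Fungal counts as a percent of fungal plus plant counts (vertical axis, linear, 0 to 100) in the 7 inoculated groups (horizontal axis); points are libraries, bars means and error bars SD (n = 3). The qko libraries lay between 51.7 and 86.6%, and the cyp libraries of day 3 between 1.06 and 8.72%.

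Infection of each line was examined by setting its inoculated libraries against its water libraries of the same day. In cyp on day 3, indolic phytoalexin genes were among the highest. CYP82C2 (AT4G31970) and CYP71A12 (AT2G30750), P450s of indole-3-carbonylnitrile synthesis, rose by 9.29 ± 1.05 and 8.81 ± 1.12, and PAD3 rose by 4.82 ± 0.57. IGMT2 (AT1G21120), a methyltransferase of indole glucosinolates, rose by 3.68 ± 0.54, and the glutathione transferase GSTF7 (AT1G02920) by 4.33 ± 0.51. Their Benjamini-Hochberg adjusted p in the edgeR quasi-likelihood test ran from 3.41e-06 to 0.000127. In the camalexin list 9 of 15 members rose (14 adjusted over the list alone), as did 6 of 17 of the indole glucosinolate list (11 alone) and 6 of 10 of the tryptophan list (8 alone). The camera adjusted p with an estimated correlation was 8.51e-05, 0.000166 and 0.00216 for these lists. 3 of 25 pattern-triggered immunity genes rose (10 alone), with adjusted p = 0.0351 with an estimated correlation, and 2 of 25 jasmonate genes (2 alone), with 0.124. Without water replicate 2, with 3 counts left in water, the CYP82C2 ratio was 1314 (95% counting interval 449.6 to 6374). Of 21862 plant genes tested, 178 rose and 3 fell, 181 in all. That count was 106 without inoculated replicate 2 and 82, 107 and 95 without water replicates 1, 2 and 3. DESeq2 called 306, and a fit of the 6 compared libraries alone called 35 and lost PAD3.

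On day 6 in cyp, CYP71A13 (AT2G30770), which acts ahead of PAD3 in camalexin synthesis, rose by 12.99 ± 1.08 and PAD3 by 7.29 ± 0.61. ASA1 (AT5G05730) and TSB2 (AT4G27070), enzymes of tryptophan synthesis, rose by 4.64 ± 0.32 and 4.52 ± 0.29. The jasmonate genes LOX4 (AT1G72520) and JAZ5 (AT1G17380) rose by 6.08 ± 0.60 and 5.16 ± 0.38, the ethylene synthesis gene ACS2 (AT1G01480) by 5.18 ± 0.44, and PR1 (AT2G14610), the usual marker of salicylic acid signalling, by 4.62 ± 1.01. SOT17 (AT1G18590), a sulfotransferase of aliphatic glucosinolates, rose by 4.09 ± 0.34. AT5G46900, a gene of the lipid transfer protein family, was among the lowest, at -3.89 ± 0.72. Single libraries moved some of these values: without water replicate 1, JAZ5 was at 5.80 and ACS2 at 5.81, and CYP71A13, then without counts in water, was at least 7597-fold higher. PR1 was at 3.29 without inoculated replicate 2 and 5.33 without water replicate 3, and AT5G46900 at -5.27 without inoculated replicate 1. Adjusted p for these genes ran from 3.78e-13 to 0.000702 (edgeR quasi-likelihood, Benjamini-Hochberg). Members rose in the camalexin (14 of 15), indole glucosinolate (14 of 17), tryptophan (8 of 10, with 1 lower), jasmonate (22 of 25), ethylene and jasmonate defence (11 of 18), pattern-triggered immunity (23 of 25) and glutathione transferase (17 of 21) lists. The counts adjusted over the list alone were 15, 14, 8, 22, 14, 24 and 18. Adjusted p with an estimated correlation ran from 0.000227 for jasmonate to 0.00924 for glutathione transferases. In the salicylic acid list 13 of 19 rose (13 alone), and in the phenylpropanoid list 14 of 17 (14 alone), with adjusted p = 0.09 and 0.0583 with an estimated correlation. In all 3953 genes rose and 2458 fell, 6411 together. The 6 compared libraries alone gave 3758, and a fold change of at least 1 on the log2 scale left 3481.

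On day 10 in cyp, PAD3 was 7.70 ± 0.63 higher than in water, MYB122 (AT1G74080), a regulator of indole glucosinolate genes, 6.02 ± 0.49 higher, and the jasmonate repressor JAZ10 (AT5G13220) 5.98 ± 0.26 higher. PR1 rose by 5.48 ± 0.90, and the plant defensin gene PDF1.2 (AT5G44420), with no counts in water, was at least 45.9-fold higher, a call that DESeq2 did not make. Genes of aliphatic glucosinolate synthesis rose, among them BCAT4 (AT3G19710) by 4.91 ± 0.76 and IMD1 (AT5G14200) by 4.37 ± 0.43. The triterpene synthase gene PEN3 (AT5G36150) fell by 5.30 ± 0.66 and the light-harvesting gene LHCB3 (AT5G54270) by 2.21 ± 0.59. The sulfur starvation marker ATSDI1 (AT5G48850) fell by 3.20 ± 0.62. ATSDI1 was at -2.61 without water replicate 1, and PEN3 at -5.95 without inoculated replicate 1. The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p from 1.61e-17 to 0.0044. Members rose in the camalexin list (14 of 15; 14 adjusted over the list alone), the indole glucosinolate list (14 of 17; 14), the tryptophan list (8 of 10, 1 lower; 8), the jasmonate list (21 of 25; 21), the ethylene and jasmonate defence list (13 of 18; 14) and the immunity list (21 of 25; 23). With an estimated correlation their adjusted p ran from 0.000274 to 0.00977. 16 of 26 aliphatic glucosinolate genes rose (16 alone; adjusted p = 0.054 with an estimated correlation), and 26 of 38 photosynthesis genes fell (28 alone; 0.365). Sulfur genes split, with 6 of 17 higher and 4 lower (6 and 5 alone; 0.446). In all 3969 genes rose and 2428 fell, or 6397 together, of which 3709 passed a log2 change of 1. The excess of higher genes depended on the filter, as without a low-count filter 3268 rose and 3263 fell.

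In qko on day 3, danger-peptide precursor genes stood beside the phytoalexin genes. PROPEP3 (AT5G64905) and PROPEP2 (AT5G64890) rose by 5.06 ± 0.55 and 4.83 ± 0.60, CYP82C2 by 7.33 ± 0.86, CYP71A13 by 5.25 ± 0.71 and PAD3 by 4.33 ± 0.59. LOX4 rose by 3.49 ± 0.54, and FMO GS-OX1 (AT1G65860), an oxygenase of aliphatic glucosinolate side chains, by 3.00 ± 0.53. The cellulase gene CEL5 (AT1G22880) fell by 1.94 ± 0.42. Without water replicate 3 the values were 5.77 for PROPEP3, 9.14 for CYP82C2 and 6.06 for CYP71A13, and PROPEP2, with 3 counts left in water, had a ratio of 77.6 (95% counting interval 26.2 to 379). Adjusted p ran from 9.05e-07 to 0.0038 (edgeR quasi-likelihood, Benjamini-Hochberg). 14 of 15 camalexin genes rose (14 adjusted over the list alone), 6 of 17 indole glucosinolate genes (7), 6 of 10 tryptophan genes (7, with 1 lower), 6 of 18 ethylene and jasmonate defence genes (8) and 7 of 25 immunity genes (16). Their adjusted p with an estimated correlation was 0.000296, 0.0441, 0.0233, 0.018 and 0.00926. 5 of 25 jasmonate genes (7 alone) and 5 of 17 phenylpropanoid genes (10 alone) rose, with adjusted p = 0.286 and 0.129 with an estimated correlation. In all 664 genes rose and 125 fell, or 789, and the count was 517 and 487 without inoculated replicates 1 and 3 and 346 without water replicate 2. The 6 compared libraries alone called 2192.

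On day 6 in qko, root and root hair markers had the lowest median of the 21 lists, at -2.78. The cell wall genes SHV2 (AT5G49270), PRP3 (AT3G62680) and LRX1 (AT1G12040), active in root hairs, fell by 5.90 ± 0.65, 5.60 ± 0.71 and 5.37 ± 0.64. AT1G52060, a jacalin lectin gene, had no counts in inoculated qko and was at least 209-fold lower than in water. PAD3 rose by 4.71 ± 0.54, CYP71A13 by 7.69 ± 0.80, the tryptophan enzyme ASB1 (AT1G25220) by 3.75 ± 0.31, JAZ5 by 5.48 ± 0.39, PR1 by 6.74 ± 0.94 and NATA1 (AT2G39030), an acetyltransferase acting on ornithine, by 11.83 ± 0.92. The sulfate transporter gene SULTR1;1 (AT4G08620) fell by 4.43 ± 0.72. Several of these values moved with water replicate 3, the library with 101163 fungal counts. Without it PAD3 was at 6.00, CYP71A13 at 8.54 and PR1 at 7.57. NATA1, at 0.123 ± 0.214 CPM in water, had counts there in replicate 3 alone; without that library it was at least 7958-fold higher, and without water replicate 2 at 11.24. SHV2 was at -6.86 without inoculated replicate 2. Adjusted p lay between 9.66e-12 and 2.98e-05 (edgeR quasi-likelihood, Benjamini-Hochberg). 12 of 15 root and root hair markers fell (13 adjusted over the list alone), with adjusted p = 0.0233 with an estimated correlation; the patterning genes SCR (AT3G54220) and SHR (AT4G37650), at -0.26 ± 0.21 and -0.40 ± 0.31, did not pass. Members rose in the camalexin (14 of 15), indole glucosinolate (12 of 17, 2 lower), tryptophan (8 of 10, 1 lower), jasmonate (17 of 25), ethylene and jasmonate defence (12 of 18) and immunity (23 of 25) lists, or 14, 12, 8, 18, 15 and 24 adjusted over the list alone. With an estimated correlation their adjusted p ran from 0.00138 to 0.0061. 13 of 19 salicylic acid genes rose (13 alone; 0.0776 as adjusted p with an estimated correlation), and 5 of 14 cell division genes fell (6 alone; 0.444). In all 3179 genes rose and 3657 fell, 6836 together, with 4.72 M plant counts in the shallowest inoculated library. Which direction held more genes was not stable. 3466 rose and 3388 fell without water replicate 1, 2594 and 2445 without inoculated replicate 3, and 1399 and 1014 from the 6 compared libraries alone, or 2413. A log2 change of at least 1 left 4265.

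In pad3 on day 3, CYP71A12 rose by 9.10 ± 1.14, CYP82C2 by 8.77 ± 1.04, CYP71A13 by 7.39 ± 0.87 and PAD3 itself by 3.98 ± 0.65. GSTU12 (AT1G69920), a glutathione transferase, rose by 6.17 ± 0.73, PROPEP3 by 4.86 ± 0.62 and ASB1 by 1.83 ± 0.29. The tonoplast aquaporin gene TIP2;3 (AT5G47450) fell by 6.71 ± 1.21, the sulfur-responsive LSU1 (AT3G49580) by 4.27 ± 0.90 and the ribonuclease gene RNS1 (AT2G02990) by 2.27 ± 0.40. Without water replicate 1, PROPEP3 was at 5.52 and CYP71A12, with 2 counts left in water, had a ratio of 1764 (95% counting interval 488 to 14568), and GSTU12 was at 7.29 without water replicate 2. TIP2;3 had inoculated counts in replicate 1 alone; without it the gene was at least 164-fold lower, and it was at -5.97 without inoculated replicate 3 and -5.43 without water replicate 1. Adjusted p ran from 1.67e-06 to 0.00383 (edgeR quasi-likelihood, Benjamini-Hochberg). 13 of 15 camalexin genes (14 adjusted over the list alone), 7 of 17 indole glucosinolate genes (8) and 7 of 10 tryptophan genes (7) rose, with adjusted p = 0.00063, 0.0361 and 0.0361 with an estimated correlation. 8 of 25 immunity genes rose (8 alone; 0.193). 3 of 38 photosynthesis genes fell (26 alone; 0.398), 4 of 17 sulfur genes fell and 1 rose (10 and 3 alone; 0.303), and 3 of 15 root markers fell (6 alone; 0.316), each p again with an estimated correlation. In all 724 genes rose and 801 fell, or 1525. The small excess of lower genes turned in other fits. 600, 208 and 867 rose and 444, 77 and 759 fell without inoculated replicates 1, 2 and 3, 196 and 75 without water replicate 1, 216 and 90 from the 6 compared libraries alone, and 854 and 554 without a low-count filter. The count was thus 285 without inoculated replicate 2, 271 without water replicate 1 and 306 from the compared libraries, against 2507 by DESeq2.

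On day 6 in pad3, CYP82C2 rose by 10.71 ± 1.04, CYP71A12 by 9.50 ± 1.05, CYP81F2 (AT5G57220), a P450 that modifies indole glucosinolates, by 5.25 ± 0.62, and PR1 by 4.35 ± 0.92. CYP71A13 stood at 837 ± 406 CPM (SD, n = 3) in inoculated libraries, with 2 counts over the whole water group. ASA1 rose by 4.01 ± 0.31, LOX4 by 4.97 ± 0.58, ACS2 by 4.49 ± 0.43, and AKN2 (AT4G39940), a kinase of sulfate assimilation, by 2.96 ± 0.25. LRX1 fell by 3.09 ± 0.57 and CYP705A5 (AT5G47990), a triterpene P450 gene, by 4.47 ± 0.67. PR1 was at 3.16 without inoculated replicate 2, and LRX1 at -2.37 without water replicate 3. Adjusted p ran from 1.03e-10 to 0.000731 (edgeR quasi-likelihood, Benjamini-Hochberg). Members rose in the camalexin (14 of 15), indole glucosinolate (11 of 17, 2 lower), tryptophan (8 of 10), jasmonate (15 of 25), ethylene and jasmonate defence (12 of 18), immunity (23 of 25) and glutathione transferase (14 of 21) lists, or 14, 11, 8, 15, 17, 24 and 17 adjusted over the list alone. Their adjusted p with an estimated correlation ran from 0.000232 to 0.00483. 12 of 19 salicylic acid genes rose (14 alone; 0.0688 as adjusted p with an estimated correlation). 9 of 15 root markers fell (9 alone; 0.132), as did 7 of 13 flavonoid genes (10 alone; 0.393) and 9 of 38 photosynthesis genes (22 alone; 0.393). In all 2748 genes rose and 1872 fell, 4620 together. The count was 2533 without inoculated replicate 2 and 2795 with a log2 change of at least 1.

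**Figure D3:**
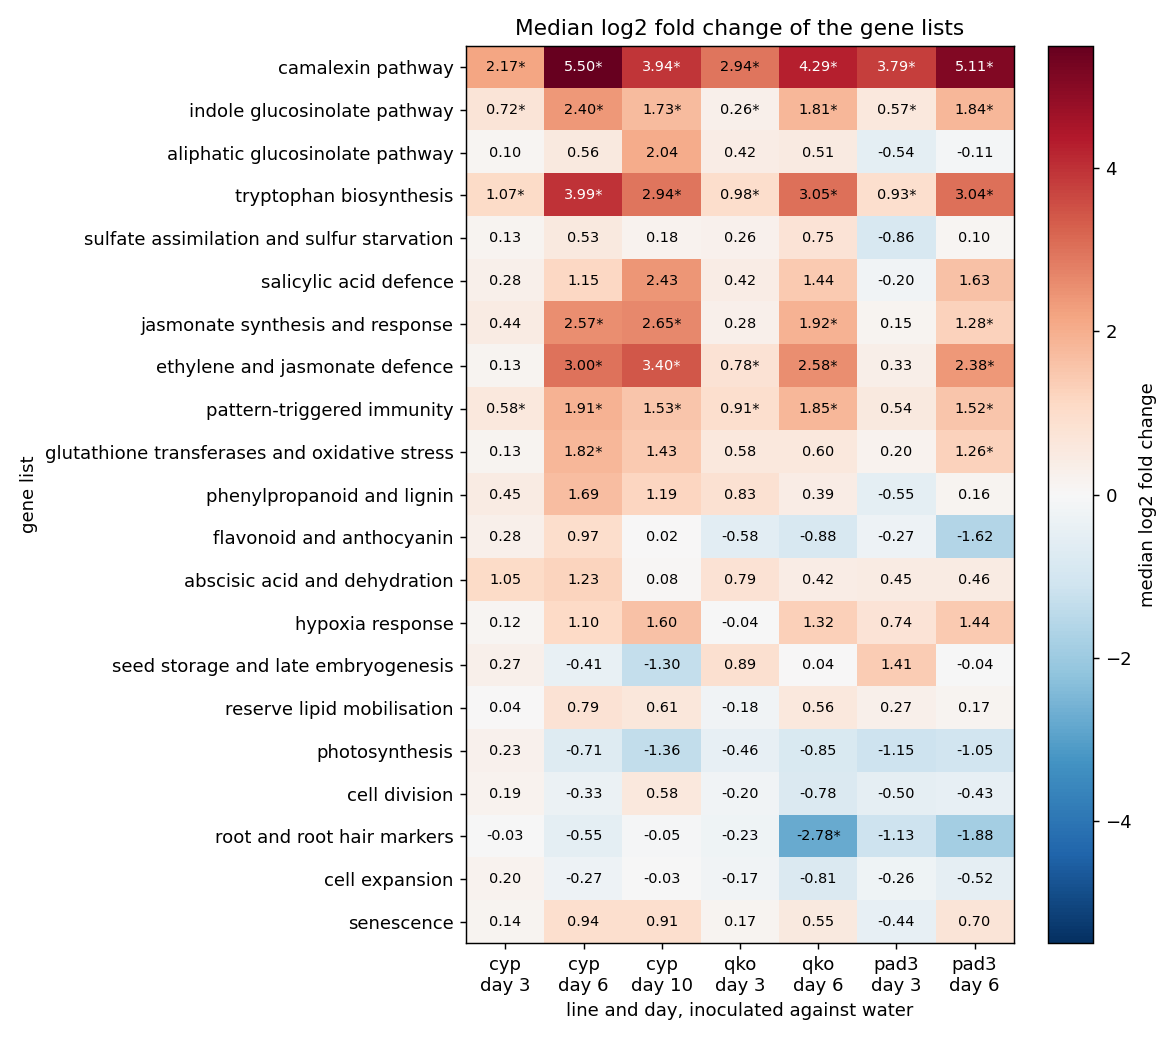
Median log2 fold change, inoculated against water (colour scale), of each of the 21 gene lists (vertical axis) in the 7 infection comparisons (horizontal axis), with an asterisk where the camera adjusted p with an estimated correlation was under 0.05. The camalexin list was highest, from 2.17 in cyp on day 3 to 5.50 in cyp on day 6, and the root markers were lowest in qko on day 6, at -2.78.

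Across the 7 infection comparisons, 109 genes rose in every comparison and none fell in every comparison. The second count could not exceed 3, the number of genes that fell in cyp on day 3. The shared set held the camalexin genes CYP71A12 and CYP71A13, the indole glucosinolate genes MYB122 and IGMT2, the glutathione transferase GSTF7 and the jasmonate gene LOX4, whose smallest rise was 1.97. PR1 passed on days 6 and 10 but in no line on day 3, where its adjusted p was 0.777 in cyp, 0.704 in qko and 0.403 in pad3 (edgeR quasi-likelihood, Benjamini-Hochberg). On day 6 the 3 lines shared 1739 higher and 570 lower genes. The cyp and qko calls of day 6 had 2300 higher genes in common, where 574.8 were expected if calls were independent. For cyp and pad3 these numbers were 2106 and 496.9, and for qko and pad3 2001 and 399.6. All calls came from 1 fit that shared the spread of each gene over the groups. Some excess was thus likely from the start, and its size does not measure a shared response. The ethylene and jasmonate defence list holds genes without counts in some water groups: with these at their lower bound, its median in cyp on day 6 was 2.02 against 3.00 as fitted, and in pad3 on day 6 1.99 against 2.38.

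Whether the lines responded differently was tested as the difference of their infection responses. Inoculated lines also differed in mean fungal share, at 4.99% in cyp, 60.2% in qko and 30.9% in pad3 on day 3. On day 6 these shares were 31.0, 75.4 and 27.3%. Effects of line and of fungal share were not separated in these tests. On day 3, TIP2;3, which had fallen in pad3, had a response 7.12 ± 1.46 higher in cyp than in pad3. AATP1 (AT5G40010), a mitochondrial ATPase gene, had a response 5.05 ± 0.81 higher in qko than in pad3, the senescence regulator NAC6 (AT5G39610) 2.61 ± 0.43 higher and the alternative oxidase AOX1A (AT3G22370) 1.84 ± 0.32 higher. AOX1A differed in water as well, at 24.2 ± 1.56 CPM in qko and 45.7 ± 5.57 in pad3, against 51.2 ± 7.38 and 26.9 ± 7.41 in inoculated libraries. AT5G22270 responded 3.69 ± 0.49 more in qko than in cyp (3.07 without cyp water replicate 2), and AATP1 was at 4.43 without pad3 water replicate 1. The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p of 0.0492 for TIP2;3 and 0.000273 to 0.00442 for the others; the TIP2;3 call was lost in 8 of the 12 fits without 1 library, all but those without cyp inoculated replicates 2 and 3 or pad3 water replicates 2 and 3. 24 genes differed between cyp and pad3 (22 higher and 2 lower in cyp), 176 between qko and pad3 (155 and 21) and 9 between qko and cyp, all higher in qko. In the qko against pad3 test, 2 of 17 phenylpropanoid genes (8 adjusted over the list alone) and 1 of 17 sulfur genes (6 alone) responded more in qko, with adjusted p = 0.165 and 0.125 with an estimated correlation. The count of 24 moved in 11 of 12 fits without 1 library, all but pad3 inoculated replicate 3, from 0 (without cyp inoculated replicate 1, any cyp water replicate, pad3 inoculated replicate 2 or pad3 water replicate 1) to 116 (without pad3 water replicate 2); 3819 genes had an unadjusted p under 0.05 in the full fit and DESeq2 called 511. The count of 176 moved in 9 of 12 fits, all but those without pad3 inoculated replicate 3 or pad3 water replicates 2 and 3, down to 25 without pad3 water replicate 1, and was 487 by DESeq2. The count of 9 was 1 without cyp inoculated replicates 1 or 3, cyp water replicate 2 or qko water replicate 2, 5 and 2 without qko inoculated replicates 1 and 3, and 36 by DESeq2.

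On day 6, jasmonate genes responded more in cyp than in pad3. The lipoxygenase LOX3 (AT1G17420) responded by 2.30 ± 0.43 more, JAZ10 by 1.80 ± 0.30 more, and IGMT5 (AT1G76790), a methyltransferase of indole glucosinolates, by 2.63 ± 0.48 more, while the transcription factor LBD29 (AT3G58190) was lower at -4.99 ± 0.86 (-5.76 without cyp inoculated replicate 3). 5 of 25 jasmonate genes passed (16 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), 1 of 17 indole glucosinolate genes (8 alone; 0.0792), 5 of 17 phenylpropanoid genes (7 alone; 0.106) and 1 of 13 flavonoid genes (8 alone; 0.189). Between qko and pad3, the ratio of inoculated to water of the glutathione transferase GSTF3 (AT2G02930) was lower in qko, at -4.62 ± 0.75, although inoculated qko held more of it, 173 ± 90.8 CPM against 113 ± 53.2. The difference lay in the water groups, at 38.6 ± 20.3 and 1.02 ± 0.322 CPM. 3 of 21 members of its list had a lower ratio (6 alone; adjusted p = 0.203 with an estimated correlation), and that of AT1G31550 was higher, at 4.34 ± 0.55. Between qko and cyp, SHV2, PRP3 and LRX1 had a lower ratio in qko, at -5.09 ± 0.79, -4.97 ± 0.87 and -4.97 ± 0.80 (-5.87, -5.60 and -5.59 without cyp water replicate 3, and SHV2 at -6.05 without qko inoculated replicate 2). Their inoculated levels were lower too, with PRP3 at 12.2 ± 3.27 CPM in qko and 193 ± 109 in cyp. CYP82C2, at -5.40 ± 1.22, and GSTF3, at -3.42 ± 0.72, also had a lower ratio in qko, but through the water groups. Inoculated CYP82C2 stood at 1810 ± 695.0 CPM in qko and 1815 ± 568.6 in cyp, and water CYP82C2 at 4.76 ± 4.70 and 0.109 ± 0.0972. GSTF3 stood at 104 ± 9.77 CPM in inoculated and 2.17 ± 0.913 in water cyp. The qko water group includes replicate 3 with its 101163 fungal counts, without which CYP82C2 was at -4.18. ACD6 (AT4G14400), which promotes salicylic acid signalling, was higher at 6.72 ± 1.09 (5.90 without cyp water replicate 1, 6.12 without qko inoculated replicate 2), with 0.0539 ± 0.0304 CPM in qko water and 1.22 ± 0.957 in cyp water. The ratio was lower in qko for 7 of 15 root markers (9 alone), 5 of 15 camalexin genes (7 alone) and 6 of 21 glutathione transferase genes (7 alone), with adjusted p = 0.0737, 0.615 and 0.354 with an estimated correlation. For the camalexin genes this was not a lower level in every case, since CYP71A12 also stood at 2532 ± 429.3 CPM in inoculated qko and 2289 ± 758.6 in cyp, against 46.8 ± 38.1 and 1.55 ± 0.897 in water. Benjamini-Hochberg adjusted p for the genes whose difference of response is given with its SE ran from 1.77e-05 to 0.00608 (edgeR quasi-likelihood).

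The day 6 counts were 246 genes for cyp against pad3 (202 with the higher response in cyp, 44 lower), 348 for qko against pad3 (53 and 295) and 1253 for qko against cyp (217 and 1036). Each moved by over 1.5 times without most single libraries. The first ran from 59 without cyp water replicate 2 to 850 without cyp water replicate 3 and moved in 9 of 12 fits, all but those without cyp inoculated replicate 1, pad3 inoculated replicate 1 or pad3 water replicate 1. It also fell by over 1.5 times with a replicate block, which pairs inoculated and water libraries of the same number. The qko against pad3 count ran from 122 without qko inoculated replicate 1 or pad3 water replicate 2 to 858 without qko water replicate 1, and moved in 10 of 12 fits, all but those without pad3 inoculated replicate 2 or pad3 water replicate 3. The qko against cyp count ran from 723 without cyp water replicate 1 to 2522 without qko water replicate 1, and moved in 8 of 12 fits, all but those without a cyp inoculated replicate or qko inoculated replicate 3. Fitted from the 12 compared libraries alone, the counts were 24, 32 and 156, LOX3, JAZ10 and CYP82C2 no longer passed, and DESeq2 gave 607 and 665 for the pair of tests against pad3.

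The change of each line's response between harvests was tested next. The mean fungal share changed as well, in cyp from 4.99 to 31.0 and 50.6% on days 3, 6 and 10. From day 3 to day 6 it went from 60.2 to 75.4% in qko and from 30.9 to 27.3% in pad3. Effects of day and of fungal share were not separated. In cyp from day 3 to day 6, the response of AT2G38240, a dioxygenase of jasmonate turnover, grew by 10.88 ± 1.57 and that of the chaperone gene BIP3 (AT1G09080) by 7.59 ± 1.55, and that of AT5G46890 was lower by day 6, at -3.94 ± 0.93. Without inoculated day 6 replicate 1, AT2G38240 was at 10.26 and AT5G46890 at -4.68, and BIP3 was at 6.05 and 8.31 without inoculated replicate 2 and water replicate 1 of day 6. The response of 16 of 25 jasmonate genes grew (18 adjusted over the list alone), with 11 of 15 camalexin (12), 10 of 17 indole glucosinolate (11), 8 of 10 tryptophan (8), 8 of 18 ethylene and jasmonate defence (9), 14 of 25 immunity (20) and 10 of 21 glutathione transferase genes (15). Adjusted p with an estimated correlation ran from 0.000155 to 0.0113. In qko, NATA1 grew by 6.51 ± 1.07 (4.12 without replicate 3 of day 3 water; without that of day 6 no water counts were left to take a value from), with 12 of 25 jasmonate genes (17 alone; 0.0019 as adjusted p with an estimated correlation) and 8 of 10 tryptophan genes (8 alone; 0.00329). 10 of 15 root markers had a lower response on day 6 (10 alone; 0.00918). In pad3, the glutathione transferase GSTU3 (AT2G29470) grew by 6.94 ± 1.40, a call lost without water day 3 replicate 3, where 3 counts were left in that group, and was at 7.66 and 6.32 without inoculated day 3 replicates 2 and 3. There 8 of 17 sulfur genes grew (10 alone; 0.0126 with an estimated correlation), and so did 8 of 10 tryptophan (8), 7 of 25 jasmonate (14), 6 of 18 ethylene and jasmonate defence (9) and 5 of 14 senescence genes (8), at adjusted p of 0.0126 to 0.018 with an estimated correlation. In cyp from day 6 to day 10 the response of the aspartate kinase gene AK3 (AT3G02020) was 5.04 ± 0.97 higher on day 10, mostly through its water groups, which stood at 12.8 ± 7.64 CPM on day 6 and 0.742 ± 0.165 on day 10, against 7.11 ± 4.45 and 13.7 ± 6.53 in inoculated libraries. There 6 of 26 aliphatic glucosinolate genes grew (11 alone; adjusted p = 0.523 with an estimated correlation). Adjusted p of the genes named ran from 2.45e-05 to 0.00565 (edgeR quasi-likelihood, Benjamini-Hochberg).

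Over all genes, 1588 responses changed in cyp from day 3 to day 6 (1389 grew, 199 were lower), 1604 in qko (637 and 967), 1070 in pad3 (870 and 200) and 500 in cyp from day 6 to day 10 (252 and 248). The cyp count was 866 without inoculated day 6 replicate 2 and 817 from the compared libraries alone. The pad3 count was 591 and 699 without inoculated day 3 replicates 1 and 2, 400 without inoculated day 6 replicate 2, 461 without water day 3 replicate 1, 488 and 658 without water day 6 replicates 2 and 3, and 1718 by DESeq2. The count from day 6 to day 10 was 151 and 815 without inoculated day 6 replicates 1 and 3, 225 and 311 without inoculated day 10 replicates 2 and 3, 160 without water day 6 replicate 2, and 279 and 191 without water day 10 replicates 2 and 3. It was 111 from the compared libraries alone and 1086 by DESeq2. Its near balance of 252 and 248 tipped the other way without replicate 3 of inoculated day 6 (341 and 474) or day 10 (155 and 156), without water day 6 replicates 1 (320 and 336) or 3 (222 and 366), and without water day 10 replicates 2 (107 and 172) or 3 (90 and 101). It was 185 and 416 without a low-count filter.

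The water groups asked how the lines differed without inoculation. 1 of these libraries, qko day 6 replicate 3, held 101163 fungal counts, of which its 10 most counted genes made up 8.19%, within the 5.86 to 12.08% of inoculated libraries. Another, qko day 6 replicate 1, lay apart from its group, at -51.08 on the first principal component against 7.3 and 15.4, with 10.14% of its plant counts in 10 genes against 5.07 and 5.71%. The qko line stood apart on both days. BGLU28 (AT2G44460), a glucosidase induced by sulfur starvation, was 9.50 ± 0.97 higher in qko than in pad3 on day 3 and 8.84 ± 0.95 higher on day 6, and the seed storage genes CRU3 (AT4G28520) and, against cyp, SESA2 (AT4G27150) were 8.70 ± 1.26 higher on day 3 and 11.05 ± 1.32 higher on day 6. SESA2 stood at 214.6 ± 271.1 CPM in qko water on day 6 and was 9.16 above cyp without replicate 1. Without pad3 replicate 1, BGLU28 was 9.56 higher on day 6. The myrosinase gene TGG2 (AT5G25980) was lower in qko than in pad3 on day 6, at -7.35 ± 1.24 (-6.76 without pad3 replicate 1). On day 3, 14 of 17 sulfur genes were higher and 3 lower in qko than in pad3 (14 and 3 adjusted over the list alone), with adjusted p = 0.00423 with an estimated correlation. 15 of 17 seed storage genes were higher (15 alone) and 36 of 38 photosynthesis genes lower (37 alone), each with adjusted p = 0.237 with an estimated correlation. On day 6, 17 of 17 seed storage genes were higher in qko than in cyp (17 alone; 0.0156 with an estimated correlation) and also than in pad3 (17 alone), where the list did not pass (0.0971). In cyp against pad3 on day 6, none of 17 passed over all genes, where edgeR called 20 in all, 1956 had an unadjusted p under 0.05 and DESeq2 called 138; 11 of 17 were lower adjusted over the list alone (adjusted p = 0.0505 with an estimated correlation). On day 6, 11 of 17 sulfur genes were higher in qko than in cyp and 1 lower (11 and 2 alone; 0.0156). Of the photosynthesis list, 1 of 38 genes on day 6 was higher in qko than in pad3 and 3 than in cyp, and the fall of day 3 was not seen (adjusted p = 0.954 and 0.809 with an estimated correlation). The named genes had adjusted p from 2.09e-08 to 9.23e-05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Counts against pad3 were 7370 genes on day 3 (3564 higher in qko, 3806 lower) and 2862 on day 6 (1725 and 1137), and against cyp 7067 (3627 and 3440) and 2504 (1490 and 1014). The day 3 balance against cyp turned to 3718 higher and 4105 lower by DESeq2, 4333 and 4582 from the 6 compared libraries alone, and 2645 and 3087 and 2266 and 2460 without cyp replicates 1 and 2. Against pad3 it turned to 3066 and 3014 without qko replicate 3. The day 3 counts were 4752 without pad3 water replicate 1 and 4542 without qko water replicate 1. The day 6 counts were 1723 without qko replicate 3 and 1700 and 1795 without pad3 replicates 1 and 2, and against cyp 1587 and 1549 without cyp replicates 1 and 2. From the compared libraries alone they were 1339 and 644.

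Between cyp and pad3 in water, genes of indole glucosinolate synthesis were higher in cyp. CYP79B3 was 2.03 ± 0.30 higher on day 3 and 1.91 ± 0.30 higher on day 6, CYP83B1 (AT4G31500), the next P450 of the indole pathway, 1.88 ± 0.23 higher on day 6, and SOT17 1.93 ± 0.32 higher on day 3. CYP79B2 was lower in cyp on day 6, at -1.20 ± 0.23, a call lost without cyp replicates 1 or 2 or any pad3 replicate. 5 of 17 indole glucosinolate genes were higher on day 3 (7 adjusted over the list alone) and 4 on day 6 (6 alone), with adjusted p = 0.00555 and 0.0432 with an estimated correlation. The aliphatic list, to which SOT17 belongs, had 2 of 26 higher on each day (10 and 3 alone) and did not pass, with adjusted p = 0.0937 and 0.265 with an estimated correlation. The named genes had adjusted p from 6.96e-05 to 0.0225 (edgeR quasi-likelihood, Benjamini-Hochberg). In all 63 genes differed on day 3 (41 higher in cyp, 22 lower) and 20 on day 6 (16 and 4). The day 3 count was 13, 114 and 30 without cyp replicates 1, 2 and 3 and 15 and 38 without pad3 replicates 2 and 3, and the day 6 count 72 without cyp replicate 3 and 4, 5 and 13 without pad3 replicates 1, 2 and 3. From the 6 compared libraries alone the counts were 174 and 0, with DESeq2 381 and 138, and 1956 genes had an unadjusted p under 0.05 on day 6 in the full fit.

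Fungal genes were compared between the inoculated lines, as CPM scaled to fungal counts. The deposited table does not pair the gene codes with names. On day 3, tig00000032_Abra11270 was lower in qko than in pad3, at -8.79 ± 0.82, and tig00000004_Abra03165 was 8.49 ± 1.21 higher. On day 6, tig00000008_Abra06232 was lower in cyp than in pad3, at -7.67 ± 0.51, and tig00000029_Abra10410 was 6.37 ± 0.97 higher in qko than in cyp (5.38 without qko replicate 2). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p from 7.58e-08 to 0.000684. Of 10266 fungal genes tested, 1964 differed between cyp and pad3 on day 3 (1027 higher in cyp, 937 lower), 3416 between qko and pad3 (1768 and 1648) and 958 between qko and cyp (603 and 355). On day 6 the counts were 53 (5 and 48), 823 (386 and 437) and 2124 (1109 and 1015). The day 3 counts were 1221 and 1283 without pad3 replicates 1 and 2, 1836 without qko replicate 2 for qko against pad3, and 563, 481 and 428 without cyp replicate 3 and qko replicates 1 and 2 for qko against cyp. The count of 53 was 15 and 13 without cyp replicates 1 and 2, 601, 32 and 27 without pad3 replicates 1, 2 and 3, and 393 by DESeq2. The count of 823 was 358 and 219 without qko replicates 1 and 2, 384 and 287 without pad3 replicates 2 and 3, 294 from the 6 compared libraries alone and 1320 by DESeq2; that of 2124 was 750 without cyp replicate 1 and 1207 and 1075 without qko replicates 1 and 2. The compared libraries alone gave 725 for cyp against pad3 and 478 for qko against cyp on day 3. Which direction held more genes turned for the counts of 1964 (761 and 814 without pad3 replicate 3), 823 (183 and 175 and 611 and 437 without qko replicates 1 and 3) and 2124 (735 and 778 and 844 and 855 without cyp replicates 2 and 3).

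Over time, fungal genes changed most in pad3 and in late cyp. From day 3 to day 6 in pad3, tig00000002_Abra02690 rose by 7.77 ± 1.06 and tig00000026_Abra09586 fell by 3.82 ± 0.55, and from day 6 to day 10 in cyp tig00000029_Abra10410 rose by 6.54 ± 0.98 and tig00000016_Abra07778 fell by 7.14 ± 1.09, at adjusted p of 0.000219 to 0.000488 (edgeR quasi-likelihood, Benjamini-Hochberg). The former was at 5.77 without day 10 replicate 3, and the latter at -6.39 without day 6 replicate 3 and -7.92 without day 10 replicate 1. 2192 genes changed in pad3 (1313 rose, 879 fell), 3489 in cyp from day 6 to day 10 (1669 and 1820), 260 in cyp from day 3 to day 6 (183 and 77) and 85 in qko (46 and 39). The pad3 count was 1261 and 1321 without day 3 replicates 1 and 3 and 1252 without day 6 replicate 3, and the late cyp count 2155 without day 6 replicate 1 and 1660 without day 10 replicate 3. The early cyp count was 115 and 169 without replicate 3 of day 3 and of day 6, 10 from the compared libraries alone and 457 by DESeq2. The qko count was 1, 23 and 1 without day 3 replicates 1, 2 and 3, 8, 15 and 275 without day 6 replicates 1, 2 and 3, 155 from the compared libraries alone and 336 by DESeq2. The direction of most genes turned for late cyp (2015 rose and 1749 fell, 1194 and 1166, and 869 and 791 without day 10 replicates 1, 2 and 3) and for qko (8 and 15 without day 3 replicate 2). For late cyp it also turned with RLE size factors, with DESeq2, without a low-count filter and in the compared libraries alone.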

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

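Of the tests in this part, the splits of the libraries, the equal loss of root cells and the depth comparison were chosen only after results were seen; the developmental, sulfur, shallow-library and within-group tests were set down earlier.

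10 results were singled out because the effect of infection differed between lines or days. On day 3, 24 genes differed in response between cyp and pad3, 176 between qko and pad3 and 9 between qko and cyp; on day 6 these were 246, 348 and 1253. Between days 3 and 6, 1588 responses changed in cyp, 1604 in qko and 1070 in pad3, and 500 changed in cyp between days 6 and 10. Each was compared with splits of the same 12 libraries. For the line differences 25 splits were made, and 3, 4 and 3 of them gave as many genes on day 3 and 3, 5 and 3 on day 6, the real ones included. The highest other splits gave 6820, 5685 and 7080 genes on day 3 and 1004, 3441 and 4646 on day 6. For the changes between days 23 splits were made, and 3, 5, 3 and 3 gave as many, with 7715, 6084, 10755 and 2671 in the highest others. The highest other splits kept all 6 inoculated and 2 of 6 water libraries in their own groups, and each other split that gave as many genes as the real one kept unequal numbers of inoculated and water libraries there. Such splits carry the plain difference between lines or days into the contrast, a structure of the samples, so they say nothing about chance for a difference of response.

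The other comparisons have 3 libraries against 3, where 10 splits are too few for a share under 0.05. For infection, the real count and the highest other were 181 and 8, 6411 and 225, and 6397 and 1 in cyp on days 3, 6 and 10, 789 and 0 and 6836 and 3455 in qko, and 1525 and 0 and 4620 and 0 in pad3. In each, 1 of 10 splits, the real one, gave as many. For water libraries they were 63 and 20 (cyp against pad3), 7370 and 1 (qko against pad3) and 7067 and 0 (qko against cyp) on day 3 and 20 and 12, 2862 and 493 and 2504 and 1186 on day 6, again 1 of 10 in each. For fungal genes they were 1964 and 10, 3416 and 0 and 958 and 0 on day 3 in that order of lines, 823 and 32 and 2124 and 0 for qko against pad3 and cyp on day 6, and 260 and 0, 2192 and 0 and 3489 and 2 over time in cyp, pad3 and late cyp, each 1 of 10. For fungal genes of cyp against pad3 on day 6 (53 and 71) and of qko over time (85 and 120), 2 of 10 gave as many.

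The first pattern weighed was the distance of the qko water libraries from the others. If qko seedlings lagged behind, genes higher in qko on day 3 would be those that fall with time. Across the 7370 genes that differed from pad3, that difference correlated with the change in cyp water from day 3 to day 6 at r = -0.341 (Spearman -0.338), and 65.1% had opposite signs; for the 7067 genes that differed from cyp, set against the change in pad3 water over the same days, the values were -0.418, -0.438 and 69.9%. A lag may thus hold for part of these genes. The sulfur genes raised in qko had a median change of 0.075 in cyp water over these days, so the predicted fall was not seen. Genes that had already fallen in cyp before day 3 would show no change in that window. A lag was therefore not excluded for the sulfur genes. Depth was excluded, as qko water libraries held 1.02 times the counts of the others.

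The second was the fall of root markers in inoculated qko on day 6. An equal loss of root cells would lower all markers alike only if each were made in root cells alone, which was not checked. Their heterogeneity was 17.8 per degree of freedom (Cochran Q). That measure also takes genes read from the same libraries as independent, so it could not exclude a loss of root cells. The root hair genes ran from -4.68 (RSL4) to -5.90 (SHV2), while SCR (-0.26) and SHR (-0.40) did not pass. The shallow library was excluded, since the median without replicate 3 was -2.47 and 12 markers were still lower. Whether root hairs were destroyed, never formed or ceased transcription was not tested.

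The third was that gene lists followed the fungal share within groups. Over 21 inoculated libraries, deviations of list means from their group means were correlated with deviations of log2 fungal over plant counts, for 4 relations with 100000 permutations within groups. Pearson r was 0.875 for camalexin (permutation p = 8e-05, adjusted 0.00032) and 0.86 for immunity (p = 0.00032, adjusted 0.000627), -0.6 for photosynthesis (p = 0.00047, adjusted 0.000627) and -0.439 for jasmonate (p = 0.0542, adjusted 0.0542). Spearman values were 0.879 (p = 0.00011, adjusted 3e-04), 0.848 (p = 0.00015, adjusted 3e-04), -0.699 (p = 0.00198, adjusted 0.00264) and -0.561 (p = 0.0312, adjusted 0.0312), and r without cyp day 3 replicate 1 and pad3 day 3 replicate 2 was 0.862, 0.835, -0.614 and -0.356. The first 3 may follow the fungal share. For jasmonate a positive r had been predicted, and both values had the opposite sign, so a rise with the fungal share was not seen. Whether the jasmonate list falls with that share stayed open. Share deviations also correlated with plant depth at r = -0.55, and no test separated share from depth.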

How the results depend on the processing

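All alternatives named here were set before results were seen, except the sign flips of the fungal share, which were chosen after seeing the data, and the cause of each move was not tested except where stated. Of 8050 gene values over 648 genes and comparisons, 6811 kept their side of the threshold, 1239 no longer passed and none reversed. All of these genes had passed in the main fit and most were picked for large changes, so a reversal was unlikely from the start. RLE size factors moved none of 33 counts by over 1.5 times, and leaving out the 10 fungal or plant genes with most counts changed no call on the fungal share. Without a low-count filter only the day 3 difference of cyp and pad3 moved in number by over 1.5 times, to 8, but directions turned or evened out: 3268 rose and 3263 fell in cyp on day 10, 854 and 554 in pad3 on day 3, 185 and 416 changed in late cyp, and fungal genes gave 424 and 353 (qko against pad3, day 6) and 1854 and 1428 (late cyp). With RLE factors water genes of qko against cyp on day 3 were 3362 higher and 3665 lower, and fungal genes 990 and 1014 (cyp against pad3, day 3), 440 and 389 (qko against pad3, day 6) and 2152 and 1331 (late cyp). A minimum log2 change of 1, which by construction calls fewer genes, left 3481 and 3709 in cyp on days 6 and 10, 4265 in qko on day 6 and 2795 in pad3 on day 6. Of 153 list calls, 40 passed with an estimated correlation.

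DESeq2 gave 306 infection genes in cyp and 2507 in pad3 on day 3. It gave differences of response of 511, 487 and 36 on day 3 (cyp against pad3, qko against pad3, qko against cyp) and 607 and 665 on day 6 against pad3. Water differences of cyp and pad3 were 381 and 138, changes 1718 in pad3 and 1086 in late cyp, and fungal counts 393 and 1320 against pad3 on day 6 and 457 and 336 over time in cyp and qko. Directions turned to 3718 and 4105 (water, qko against cyp, day 3), 1212 and 1228 (fungal, cyp against pad3, day 3), 703 and 617 (fungal, qko against pad3, day 6) and 2380 and 1557 (fungal, late cyp).

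Fits of the compared libraries alone used the filter, scaling and spread of those libraries and had fewer residual degrees of freedom. Some counts rose and others fell. Infection counts were 35 and 3758 in cyp on days 3 and 6, 2192 and 2413 in qko, and 306 in pad3 on day 3. Differences of response were 0, 271 and 14 on day 3 and 24, 32 and 156 on day 6; beside that 0, edgeR called 24 with all libraries, 3819 genes had an unadjusted p under 0.05 there, and DESeq2 called 511. Water differences were 174 and 0 for cyp and pad3 (edgeR with all libraries 20 on day 6, 1956 at an unadjusted p under 0.05, DESeq2 138), 1339 for qko and pad3 and 644 for qko and cyp on day 6. Changes were 817 in cyp and 111 in late cyp. Fungal counts were 725 (cyp against pad3) and 478 (qko against cyp) on day 3, 294 (qko against pad3) on day 6, and 10 and 155 over time in cyp and qko. Directions turned to 1399 and 1014 in qko on day 6, 216 and 90 in pad3 on day 3, 4333 and 4582 for water qko against cyp on day 3, and, over time in fungal genes, 50 and 105 in qko and 1712 and 1517 in late cyp.

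With a replicate block, counts for the groups whose numbers pair were 6435 (cyp infection, day 6) and 64 (fungal cyp against pad3, day 6). No named gene changed its call there, and the flavonoid list was added to the lists passing the preset correlation (18 in place of 17). For infection, line differences and changes, the block paired same-numbered libraries within a line and day. Fungal and water comparisons had 1 effect per number, common to all groups of the fit. The count of 64 thus does not test pairing of cyp and pad3 on day 6 alone. Elsewhere the numbers were not taken to pair libraries, though a shared batch was not excluded, and some of these comparisons include the cyp groups of day 6. There the block gave 145 and 6333 for cyp infection on days 3 and 10, 825 and 6839 in qko, and 1622 and 4667 in pad3. Line differences were 7, 125 and 10 on day 3 and 126, 275 and 979 on day 6. Water differences were 109, 7481 and 7246, then 18, 3092 and 2636. Changes were 1544, 1481, 980 and 382 (cyp, qko, pad3, late cyp). Fungal counts were 2048, 3510 and 1215 on day 3, 879 and 2221 against qko on day 6, and 285, 84, 2214 and 3508 over time (cyp, qko, pad3, late cyp). The block passed 155 lists. For the fungal share, the replicate block took the form of an exact permutation test that flips the signs of same-numbered differences, which leaves the values at 1.42 (days), -1.48 (cyp against pad3), 2.65 (qko against pad3) and 4.13 (qko against cyp) and gave p = 0.0547, 0.219, 0.0625 and 0.0312, adjusted 0.0833, 0.219, 0.0833 and 0.0833. The qko differences thus no longer passed; 64 flips allow no p below 0.0312.

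Leaving out 1 library left 2 in a group, assumed to vary like the others. The ranges were 82 to 226, 4330 to 6367 and 4486 to 5947 for infection of cyp, 346 to 653 and 5039 to 7652 of qko, and 271 to 1626 and 2533 to 4598 of pad3. Line differences ranged over 0 to 116, 25 to 227 and 1 to 10 on day 3 and 59 to 850, 122 to 858 and 723 to 2522 on day 6. Water differences ranged over 13 to 114, 4752 to 7006 and 4542 to 6365, then 4 to 72, 1700 to 3789 and 1549 to 2865. Changes ranged over 866 to 1972, 1105 to 2076, 400 to 1174 and 151 to 815. Fungal counts ranged over 1221 to 1969, 1836 to 3387 and 428 to 936 on day 3, 13 to 601, 219 to 1048 and 750 to 1906 on day 6, and 115 to 250, 1 to 275, 1252 to 1973 and 1660 to 3764 over time. The fungal share ranged over 1.25 to 1.56 (days), -1.87 to -1.27 (cyp against pad3), 1.99 to 3.80 and 3.46 to 5.08 (qko), the last 2 no longer passing because 36 arrangements allow no p below 0.0556.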

Other observations

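Single members of some lists not described so far changed on the later days, though none of these lists passed with an estimated correlation. Of 13 hypoxia genes, 4 rose in cyp on day 6 (8 adjusted over the list alone), 7 on day 10 (9), 6 in qko on day 6 (7) and 7 in pad3 on day 6 (9). Adjusted p with an estimated correlation was 0.532, 0.368, 0.497 and 0.393. HB1 (AT2G16060), a hemoglobin induced by low oxygen, rose by 3.68 ± 0.98 in cyp on day 10 (5.05 without water replicate 1; n = 3 against 3; edgeR quasi-likelihood, Benjamini-Hochberg). Of 12 reserve lipid genes, 10 rose in cyp on day 6 (10 alone), 7 on day 10 (7) and 5 in qko on day 6 (5), with adjusted p = 0.132, 0.365 and 0.287 with an estimated correlation. ACX1 (AT4G16760), an oxidase of fatty acid breakdown, rose by 1.72 ± 0.21 in cyp on day 6.

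Of 16 abscisic acid genes, 6 rose in cyp on day 6 (7 adjusted over the list alone; adjusted p = 0.419 with an estimated correlation). Of 11 cell expansion genes in qko on day 6, 2 rose and 5 fell (median -0.81; 0.409 with an estimated correlation). EXPA5 (AT3G29030), a cell wall loosening gene, fell by 1.96 ± 0.43 in cyp on day 6 (n = 3 against 3).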
